A study of Mus musculus with 2 samples.

How the data were processed

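The series holds 2 libraries of RNA labelled as from mammary gland basal cells that were sorted by flow cytometry from wild type C57BL/6 mice 8 weeks of age. Per the labels, cells were lysed in a Smart-seq reagent, RNA was taken up with Trizol, and libraries were made with a stranded KAPA kit and sequenced on an Illumina instrument. The antibodies, the gates, the number of mice and the number of cells are not given in the sources used here. The series describes Pd-l1 positive and Pd-l1 negative basal cells. The labels give the libraries the titles W1 and W2 and are otherwise the same, so both were left unassigned and no comparison of Pd-l1 classes was made. No value in the tables was used to assign a library.

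Per the submitters' processing notes, Bowtie 0.12.2 was used and the genome builds mm8 and GRCm38 are named, without a role for either. The tool that counted reads, the annotation and the use of strand are not given in the sources used here. The deposited tables give TPM and FPKM for 137767 mouse transcripts named by Ensembl identifiers without version numbers. The deposited TPM values sum to 1000000 per library within rounding. The deposited FPKM values are the same quantities before that scaling, since TPM was FPKM times 1.00852 in library W1 and 1.24567 in library W2. The 2 value columns of each table were used and 0 other columns were present.

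Transcripts were matched by identifier to GENCODE M21 on GRCm38, which may not be the annotation the authors used. A total of 137654 identifiers matched, and the 113 without a match held 0.025% and 0.0066% of TPM in libraries W1 and W2. Values of a gene are sums over its listed transcripts, and coordinates are those of M21. The sums covered 54438 genes, of which 15809 were above 0 in at least 1 library. Where a symbol belonged to several gene identifiers, which happened for 5 genes above 0, the one with the most reads stood for it in lists.

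Depth was recovered from the FPKM values. FPKM times the annotated length of the transcript falls on whole multiples of 1 step per library, the value of 1 read. This gave 3055773 counted reads for library W1 and 3800073 for library W2. Within a tolerance of 0.1 read, 98.11% and 97.74% of the transcripts above 0 came out whole, and 99.36% and 99.26% of those under 50 reads. On simulated libraries the same procedure returned 100% of the simulated reads. Each gene's reads were used for intervals and floors. Intervals on a ratio of reads are exact Clopper-Pearson intervals at 95%, scaled to TPM, and can differ from the ratio of TPM in genes with isoforms of different length. A library with 0 reads on a gene was given a floor of 3 reads. These cover counting error only, because the protocol amplifies cDNA and names no molecular identifiers.

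The counting affects which genes can be read. Among transcripts with over 500 50-mers found in no other listed transcript, 36.41% had a read in at least 1 library. Among transcripts with 0 such 50-mers that belong to genes with several listed transcripts the share was 0.44%, and in genes with 1 listed transcript it was 7.55%. By these shares, reads that fit several isoforms of a gene were mostly not counted. Close copies of other transcripts were not all left uncounted, since Gm23935, with 0 such 50-mers, had 47916 reads in library W1 and 7185 in library W2. Genes with many overlapping isoforms are undercounted in both libraries. Gapdh, which is expressed in nearly all cells, stood at 2.01 and 0.897 TPM, and Ppia at 0.463 and 0.28 TPM. Levels of different genes should not be ranked against each other for this reason, and a gene listed at 0 in both libraries is not shown to be silent. For the same transcript, this affects both libraries alike. A gene's sum can still be affected differently in each library if the libraries use different isoforms.

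The statistic for each gene was the log2 ratio of TPM + 1 in library W1 over library W2, which understates the ratio of low genes. Genes at 1 TPM or more in at least 1 library were compared and a gene was called higher at 2-fold or more on that scale. With 1 library of each there is no test and no p-value across genes. For 31 gene lists fixed before the data were examined, the median log2 ratio of members passing the same filter was set among medians of 10000 random lists of the same size, matched on mean log2 expression in 20 bins. A list with at least 5 such members stood apart below percentile 2.5 or above the matching upper percentile. Lists of lymphatic and of venous or activated endothelial markers were added after the values were seen. Calculations used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.

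The steps were tested on simulated libraries with the real depths and mean levels of W1 and W2. All 100 genes given a 4-fold difference and all 100 given an 8-fold difference passed the 2-fold rule. These were drawn only from genes whose mean level gave at least 20 expected reads at the depth of library W1. The simulation held counting error alone, so such recovery was likely from the start. Recovery of genes with fewer reads was not tested. Of 11652 genes given no difference, 572 passed the 2-fold rule by counting error alone, and of 7742 of them with at least 20 reads in a library 23 did. Of 200 random lists of 12 genes, 4% fell outside the central 95%.

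Genes named in the text follow a rule fixed before the data were examined. It takes Cd274 first, and from each list up to 4 members with a mean of at least 10 TPM and the largest ratios. From marker lists with fewer than 2 such members it takes up to 2 with the highest TPM. In each direction it takes the 8 largest ratios among genes at 1 TPM or more in both libraries and 20 TPM or more in the higher one, and the 6 with the highest TPM among genes at 20 TPM or more in 1 library and under 1 TPM in the other. Predicted genes, taken as symbols of Gm and digits, ending in Rik or holding -ps, are passed over there, as are ribosomal protein genes and pseudogenes, and the FPKM table must give the same direction. The 10 genes with the highest mean TPM come last. Other genes were chosen after their values were seen. Among them are Krt5, Itga6, Itgb1, Trp63, Cd24a, Procr, Fos, Flt1, Pecam1, Ifnar1, Cav1, Cald1, Smtn, Gapdh, Ppia, Xist, Marco, Madcam1, mt-Rnr1, mt-Rnr2 and the members of both added lists.

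Alternatives fixed beforehand were the FPKM table, pseudocounts of 0.1 and 5, a filter at 5 TPM or none, a rescaling of library W2 by the median ratio of genes at 10 TPM or more in both libraries, a rescaling without mitochondrially encoded and ribosomal protein genes, a 4-fold threshold, genes at 1 TPM or more in both libraries, and the mean of list members. Added after the data were seen were protein-coding genes alone, genes with 1 listed transcript, and genes with at least 20 reads in a library.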

Results

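RNA was profiled in sorted cells labelled as basal cells of the mammary gland, the outer epithelial layer that includes the contractile myoepithelial cells. By the labels, the cells came from wild type C57BL/6 mice 8 weeks of age and were processed by Smart-seq II, a full-length cDNA method for very small inputs. The series set out to describe basal cells with and without surface Pd-l1, the ligand of the inhibitory T cell receptor Pd-1, which is encoded by Cd274. It holds 2 libraries, named library W1 and library W2 after their titles. All other labels of the 2 libraries were identical, so neither could be placed in the Pd-l1 positive or the Pd-l1 negative class. The values below therefore describe 2 single libraries side by side. No library has a replicate, no p-value is given, and a difference between the libraries cannot be read as a difference between Pd-l1 classes. Library W1 held 3055773 counted reads and library W2 held 3800073, as recovered from the steps between the deposited values. Intervals are exact 95% intervals on reads and cover counting error only, since the reads carry no molecular identifiers.

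Cd274, the sorting marker of the study, was read in library W1 and not in library W2. The gene (ENSMUSG00000016496.7, chromosome 19, 29367455 to 29388095, plus strand, GRCm38) stood at 59.1 TPM in library W1, from 649 reads. Library W2 had 0 reads on it, and with a floor of 3 reads the level in library W1 was at least 218-fold higher. The log2 ratio of TPM + 1 was 5.91. Cd274 has 1 listed transcript, so its value does not depend on how reads were shared among isoforms. This value was not used to assign either library to a class. Markers of endothelial cells were higher in the same library, as given below.

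Of 12587 genes at 1 TPM or more in at least 1 library, 4370 were 2-fold or more higher in library W1 and 4142 were 2-fold or more higher in library W2, together 67.63% of the genes compared. That share was 36.71% with a pseudocount of 5 and 45.56% among genes at 1 TPM or more in both libraries. With predicted genes (symbols of Gm and digits, ending in Rik or holding -ps), ribosomal protein genes and pseudogenes passed over, the genes with the most TPM in library W1 and under 1 TPM in library W2 were Lrg1 (3026 TPM, a secreted glycoprotein), Lyve1 (2408 TPM, a hyaluronan receptor of lymphatic vessels), Cldn5 (1590 TPM, an endothelial tight junction protein), Thbd (1120 TPM, thrombomodulin), Nts (682 TPM, neurotensin) and Cdh5 (584 TPM, VE-cadherin). Each of these 6 had 0 reads in library W2. In the other direction the genes kept by the same rule were Krt17 (12795 TPM), Krt8 (1691 TPM), Plet1os (1514 TPM), Epcam (1511 TPM), Krt14 (1205 TPM) and Plet1 (872 TPM), with at most 2 reads each in library W1. Neither order is a ranking of true levels, since counting was uneven between genes. Plet1os lies antisense to Plet1, and the pair cannot be told apart unless the counting used strand, which is not given in the sources used here.

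Among genes at 1 TPM or more in both libraries and 20 TPM or more in the higher one, with the same classes passed over, the largest ratios toward library W1 belonged to Plvap (409-fold, interval 285 to 611), which encodes a component of endothelial fenestrae, and S1pr1 (310-fold, 213 to 471), a sphingosine 1-phosphate receptor. Il2rg, the common cytokine receptor gamma chain, followed at 250-fold (152 to 448). Ubd, Rasip1, Ch25h, Art3 and Apold1 lay between 146-fold and 74.8-fold. Toward library W2 the largest were Acta2 (3032-fold, 2199 to 4306), smooth muscle actin, and Tagln (1218-fold, 712 to 2287), transgelin. Sfn, Myl9, Ptx3, Krt18, Alpl and mt-Nd4l completed this group, with ratios between 835-fold for Sfn and 112-fold for mt-Nd4l. The level of mt-Nd4l is uncertain because the transcript has 3 50-mers of its own. Across the 12587 genes, log2(TPM + 1) of the 2 libraries had a Pearson r of 0.549 and a Spearman rho of 0.404. Genes are not independent replicates. Pearson r was 0.328 with a pseudocount of 0.1 and 0.681 with a pseudocount of 5.

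**Figure D1:**
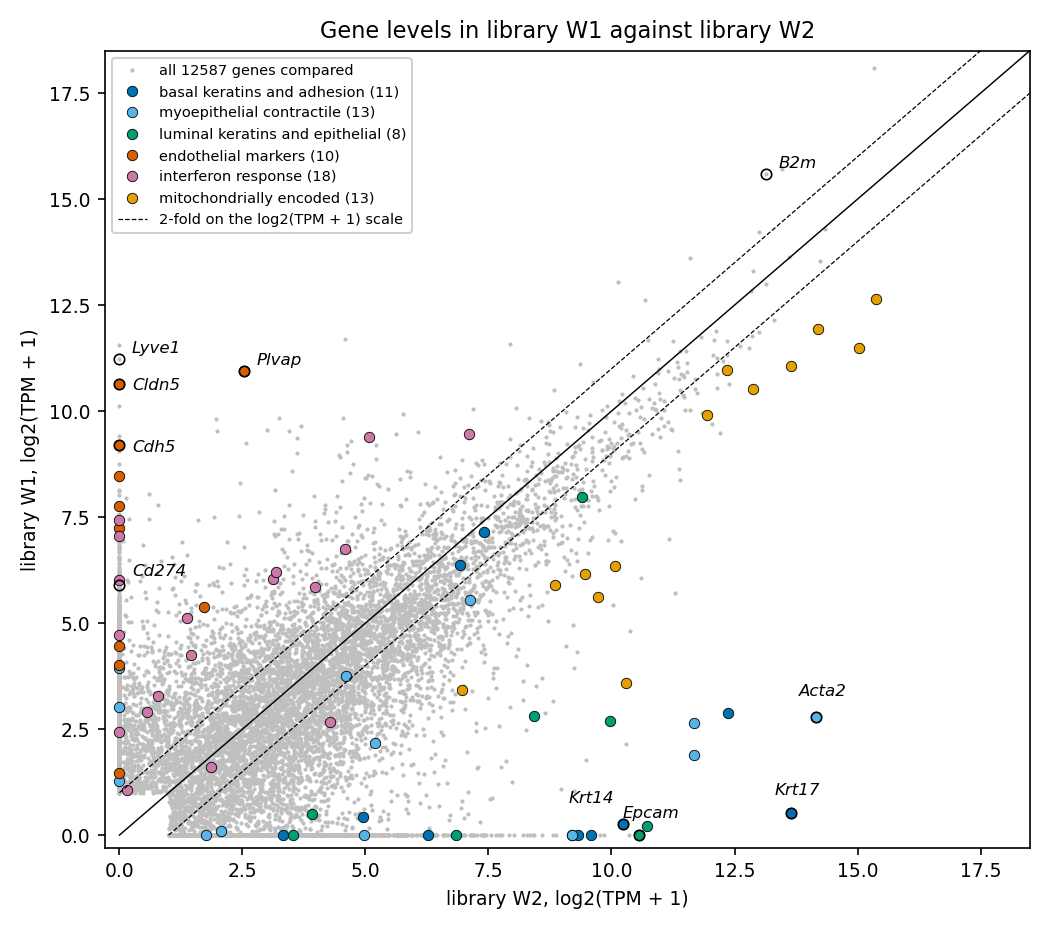
Each grey point is 1 of the 12587 genes compared, with log2(TPM + 1) in library W2 on the horizontal axis and in library W1 on the vertical axis, coloured points are members of 6 fixed lists, and dashed lines mark 2-fold. Endothelial markers such as Cldn5 (1590 TPM against 0 reads) lie along the vertical axis, and Krt17 (0.43 against 12795 TPM) and Acta2 (5.93 against 18192 TPM) lie near the horizontal one.

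Most transcripts of basal and contractile epithelial cells were lower in library W1 than in library W2. Of 11 compared members of the list of basal keratins and adhesion genes, 9 were higher in library W2, 0 were higher in library W1 and 2 lay within 2-fold. The median log2 ratio was -9.20, at percentile 0.0 of 10000 random lists matched on expression. Krt14, a keratin of the basal layer (ENSMUSG00000045545.8, chromosome 11, 100203162 to 100207548, minus strand), had 1 read in library W1 and 6230 in library W2. Its partner keratin Krt5 had 0 and 3923 reads, at least a 1299-fold difference, and Krt17 had 2 and 60538. The cell surface integrins Itga6 (140 and 170 TPM) and Itgb1 (81.8 and 120 TPM) were the 2 members within 2-fold. Trp63, a transcription factor of basal cells, was listed at 0 in both libraries. This does not show that it was silent, since reads shared between isoforms were mostly not counted.

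The myoepithelial contractile list followed the same direction, with 9 of 13 members higher in library W2 and 3 higher in library W1. Its median log2 ratio was -1.97, at percentile 0.04. Acta2 (ENSMUSG00000035783.9, chromosome 19, 34241090 to 34255590, minus strand) stood at 5.93 TPM in library W1 and 18192 TPM in library W2. Cnn1, calponin, had 0 and 4256 reads, and Myl9 was 622-fold higher in library W2 (394 to 1051). The 3 members higher in library W1 were Cav1 (14.3 TPM), Cald1 (7.11 TPM) and Smtn (1.43 TPM), all with 0 reads in library W2. Only 2 of the 15 genes of this list have 1 listed transcript. Reads shared between isoforms were mostly not counted, so 0 reads in library W2 does not show that these 3 genes were silent there.

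Luminal and general epithelial genes were also higher in library W2. All 8 compared members of the luminal keratin list were higher there, with a median log2 ratio of -6.23 at percentile 0.0. Krt8 stood at 0.169 and 1691 TPM in libraries W1 and W2, and Krt18 at 5.51 and 995 TPM. Epcam, a surface adhesion molecule of epithelial cells, had 0 and 9404 reads, at least a 3113-fold difference. Cd24a showed the smallest difference of the 8, at 251 and 673 TPM. In the hormone-sensing luminal list 4 of 5 members were higher in library W2 (median -1.81, percentile 0.805), led by the transcription factor Gata3 (0.411 and 135 TPM). That list had a percentile of 3.61 when genes with under 20 reads in both libraries were left out. The luminal progenitor and alveolar list did not stand apart, with 2 of 5 members higher in each library. Cd14 was higher in library W1 (221 and 17.1 TPM), Kit had 67 and 0 reads, and the iron-binding protein gene Lcn2 had 0 and 112 reads.

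Endothelial genes had the reverse distribution. All 10 compared members of the endothelial marker list were higher in library W1, with a median log2 ratio of 7.51 at percentile 100. Cldn5, Cdh5 and the vascular endothelial growth factor receptors Kdr and Flt1 had 6822, 6815, 6302 and 2810 reads in library W1, and 0 reads each in library W2. For Cldn5 (ENSMUSG00000041378.2, chromosome 16, 18776847 to 18778262, plus strand) the difference was at least 2290-fold. Plvap stood at 1957 and 4.78 TPM. Pecam1, the gene of the endothelial surface protein Cd31, stood at 20.95 TPM in library W1 with 0 reads in library W2.

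**Figure D2:**
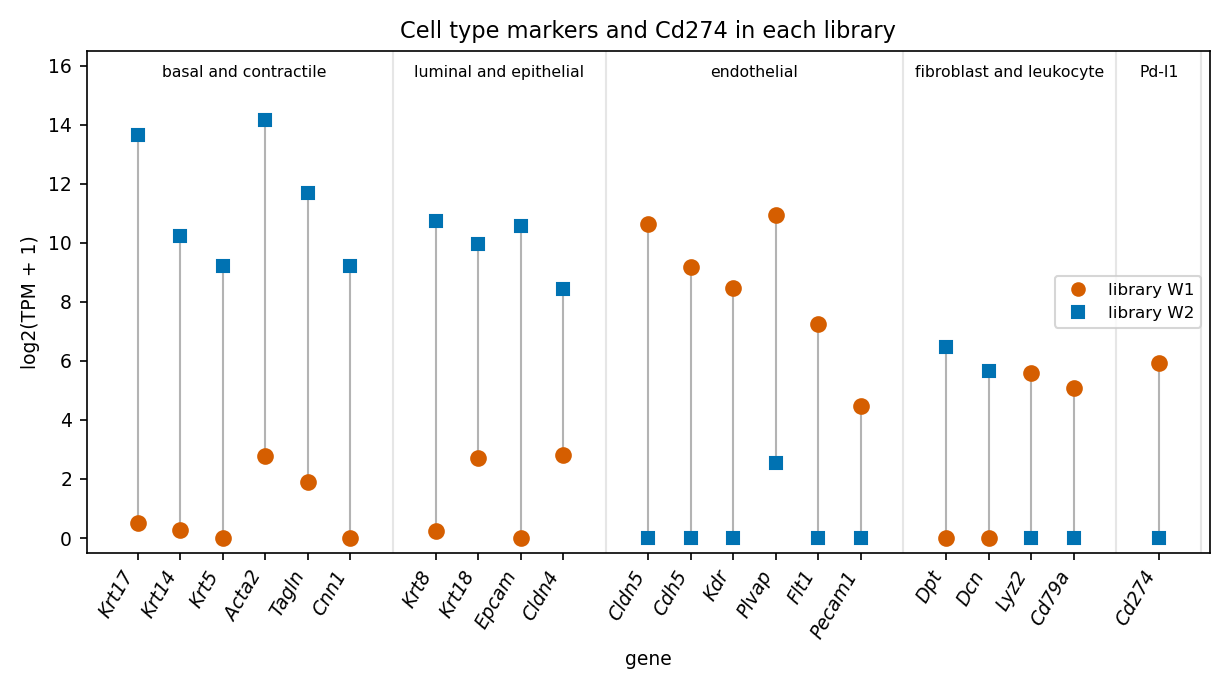
Log2(TPM + 1) on the vertical axis is drawn for named markers on the horizontal axis, with a circle for library W1 and a square for library W2 joined by a line for each gene, and each point is a single library without an error bar. Basal, contractile and luminal genes such as Krt14 (0.194 and 1205 TPM) sit high in library W2, and endothelial genes such as Plvap (1957 and 4.78 TPM) and Cd274 (59.1 and 0 TPM) sit high in library W1.

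Markers of other cell types lay in both directions. Fibroblast markers were higher in library W2 in 6 of 7 members (median -3.08, percentile 0.13), among them Dpt (0 and 87.1 TPM), Dcn (0 and 49.97 TPM) and Col1a1 (0 and 33.4 TPM), which encode matrix proteins. Leukocyte markers were higher in library W1 in 4 of 6 members (median 2.59, percentile 98.13), including lysozyme Lyz2 (46.6 and 0 TPM) and the B cell receptor component Cd79a (32.8 and 0 TPM). The leukocyte list no longer stood apart with a pseudocount of 5 (percentile 95.68) or without the filter on low values (percentile 82.77). The 14 annotated leukocyte markers with 0 reads in both libraries give no information on their own, since isoforms that share sequence were undercounted. Pericyte, adipocyte and erythroid lists had 2, 2 and 1 members at 1 TPM or more, too few for a percentile. Their leading members were Rgs5 (59.2 and 51.3 TPM), Vtn (0 and 5.26 TPM), Fabp4 (7.68 and 0 TPM), Car3 (0.237 and 3.36 TPM) and Itga2b (4.05 and 0.677 TPM), and Pf4 had 1 read in library W1.

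Interferon response genes were higher in library W1, the library that also held the endothelial transcripts. Of 18 members, 15 were higher in library W1 and 1, the receptor gene Ifnar1 (5.36 and 18.4 TPM), was higher in library W2. The median log2 ratio was 2.65 at percentile 100. Ifit3 (911 and 0 reads), Ifit2 (739 and 0 reads), the antiviral enzyme gene Oas1a (145 and 0 reads) and the chemokine gene Cxcl9 (1163 and 0 reads) were the members with the largest ratios. Cxcl9 was at least 390-fold higher in library W1.

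Antigen presentation genes tended in the same direction with less separation, and the markers of endothelial cells (median 7.51) and leukocytes (median 2.59) were higher in the same library. In the MHC class I list 7 of 11 members were higher in library W1 and 1 in library W2, and the list did not stand apart (median 1.13, percentile 96.79). It passed the limit under 6 alternatives, at percentiles from 98.23 to 99.31. B2m, the light chain of MHC class I, reached 49195 TPM in library W1 and 9054 TPM in library W2, a 5.43-fold difference (5.36 to 5.51). H2-D1 differed 3.86-fold (3.77 to 3.94), the trimming enzyme gene Erap1 3.19-fold (2.71 to 3.78) and Tapbp 2.10-fold (1.95 to 2.26), all toward library W1. H2-D1 shares sequence with other MHC genes, so its level is uncertain. The MHC class II list stood apart by a narrow margin (median 1.97, percentile 97.67), with 3 of 5 members higher in library W1 and 1 higher in library W2. H2-Eb1 was 5.34-fold higher in library W1 (4.26 to 6.76), H2-Ab1 was 4.27-fold higher (3.52 to 5.21), and H2-DMa stood at 13.2 and 14.97 TPM. That list lost its place under 6 alternatives, at percentiles from 88.38 to 97.46.

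Checkpoint genes went both ways. Of 12 members, Cd274 among them, 5 were higher in library W1 and 4 in library W2, and the list did not stand apart (median 0.26, percentile 68.21). Nectin2 (4.43-fold, 4.01 to 4.91) and Cd47, which encodes a signal against phagocytosis (4.16-fold, 3.86 to 4.50), were higher in library W1. Nt5e stood at 6.88 and 14.4 TPM, just under the 2-fold rule on the TPM + 1 scale. In the NF-kB and inflammatory list 8 of 15 members were higher in library W1 and 5 in library W2 (median 1.13, percentile 96.865), with Csf1 (43.5 and 7.77 TPM) and Nfkb1 (17.9 and 3.10 TPM) on one side, and the adhesion molecule gene Icam1 (241 and 1422 TPM) and the chemokine gene Cxcl1 (5.82 and 31.7 TPM) on the other. This list passed the upper limit for standing apart with either other pseudocount (99.2 and 98.6) and without mitochondrially encoded and ribosomal protein genes (98.01).

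Notch and Wnt pathway genes lay on opposite sides. In the Notch list 6 of 10 members were higher in library W1 and 0 in library W2 (median 1.95, percentile 99.97), among them the ligand gene Dll4 (101.5 TPM and 0 reads), the receptor gene Notch1 (70.5 and 12.8 TPM) and the targets Hes1 (1075 and 265 TPM) and Nrarp (18.9 and 2.41 TPM). The endothelial markers moved with this list. In the Wnt list 13 of 17 members were higher in library W2 and 2 in library W1 (median -1.75, percentile 0.26). The ligand gene Wnt10a (0 and 139 TPM), Dkk3 (0 and 120 TPM) and the receptor gene Lgr5 (0.119 and 32.5 TPM) were higher in library W2, and the cyclin gene Ccnd1 (253 and 14.6 TPM) was higher in library W1. Lists of basal and luminal epithelial genes moved with the Wnt list.

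Genes reported to mark mammary stem cells were divided. Of 16 members, 7 were higher in each library, and the list did not stand apart (median -0.36, percentile 38.33). Lgr6 (0 and 34.9 TPM), Lgr5 and the transcription factor Snai2 (17.8 and 265 TPM) were higher in library W2. Cdh5, Zeb1 (128 TPM and 0 reads), Nrp1 (45.3 and 0.091 TPM) and Procr (25.1 and 2.65 TPM) were higher in library W1. Cdh5 is also on the endothelial list. In the EMT and TGF-beta list 8 of 17 members were higher in library W1 and 5 in library W2 (median 0.01, percentile 68.75), where Cdh1, E-cadherin, had 0 and 629 reads and Tgfb3 stood at 1.56 and 25.4 TPM.

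All 13 mitochondrially encoded messenger RNAs were higher in library W2, with a median log2 ratio of -2.95 at percentile 0.0. The basal keratin (median -9.20), luminal keratin (-6.23) and fibroblast (-3.08) lists were higher in the same library, and endothelial markers (7.51) were higher in library W1. The mitochondrial messenger RNAs made up 2.0% of all TPM in library W1 and 12.9% in library W2. Among the well separated members, mt-Co1 stood at 6367 and 42665 TPM, mt-Cytb at 2887 and 33607 TPM and mt-Nd1 at 3920 and 18887 TPM. The ratios of mt-Nd4l, mt-Co3 and mt-Atp6 were larger, at 112-fold, 17.4-fold and 13.4-fold, yet these transcripts have 3, 1 and 3 50-mers of their own and their reads are uncertain. For mt-Atp8, with 155 such 50-mers, the ratio was 12.7-fold (5.60 to 35.8). Nuclear genes of oxidative phosphorylation did not stand apart (4 of 19 members higher in library W1 and 8 in library W2, median -0.51, percentile 33.48), with Uqcrc1, Atp5b, Sdhb and Ndufb5 higher in library W2 by 5.59-fold, 3.37-fold, 2.42-fold and 2.87-fold.

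The lists of cell cycle genes did not stand apart as defined. G2/M genes were higher in library W1 in 7 of 9 members (median 1.85, percentile 91.525), with Ube2c at 24.6 and 6.10 TPM and Ccna2 at 19.9 and 8.18 TPM. The G2/M list passed the limit with a pseudocount of 5 (percentile 99.59) and without the filter on low values (97.67). S phase genes were higher in library W2 in 5 of 12 members and in library W1 in 3 (median 0.05, percentile 62.34), including Ccne1 (5.28 and 49.7 TPM), Mcm4 (3.86 and 30.9 TPM), Rpa2 (10.2 and 38.5 TPM) and Pcna (19.4 and 60.4 TPM). Of 14 inhibitors and quiescence genes, 3 were higher in each library (median -0.26, percentile 54.78). In that group Gas1 (0.446 and 57.3 TPM) and Gas6 (99.5 and 327 TPM) were higher in library W2, while Btg1 (245 and 130 TPM) and Klf4 (327 and 182 TPM) differed by less than 2-fold. Targets of p53 came close to the limit (7 of 11 higher in library W2 and 0 in library W1, median -1.28, percentile 4.615), with Phlda3 (0.23 and 159 TPM), the death receptor gene Fas (18.2 and 111 TPM), Sesn2 (22.98 and 69.3 TPM) and Ccng1 (12.3 and 25.9 TPM).

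Of 17 immediate early and dissociation stress genes, 4 were higher in library W1 and 6 in library W2 (median -0.55, percentile 40.865). Fosl1 (41.8 and 1038 TPM) and Nr4a1 (7.31 and 37.7 TPM) were higher in library W2, Fosl2 (229 and 80.7 TPM) and Dusp1 (44.8 and 14.9 TPM) were higher in library W1, and Fos was abundant in both (2547 and 4295 TPM). In the glycolysis list 4 of 14 members were higher in library W1 and 5 in library W2 (median -0.30, percentile 35.88), with Pfkp (35.4 and 1.21 TPM), Hk2 (3.59 and 18.49 TPM), Pgam1 (200.3 and 356 TPM) and Pfkl (22.96 and 37.6 TPM). Basement membrane and matrix genes were higher in library W1 in 4 of 12 members and in library W2 in 3 (median 0.32, percentile 66.06). Nid1 was 11.02-fold higher in library W1 (9.83 to 12.4), Col4a1 and Col4a2 stood at 14.3 and 137 TPM there against 6.02 and 70.3 TPM, and Fbln1 had 0 and 238 reads. Hedgehog and Hippo target genes were higher in library W1 in 1 of 10 members and in library W2 in 4 (median -0.54, percentile 32.44), with Smo at 5.63 and 24.9 TPM, Lats2 at 13.7 and 25.1 TPM, and Ccn1 at 553 and 658 TPM. Housekeeping genes were higher in each library in 2 of 11 members (median -0.39, percentile 58.195), among them Actb (230 and 96.6 TPM), Eef1a1 (147 and 302 TPM), Hprt (278 and 425 TPM) and Rplp0 (561 and 778 TPM).

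**Figure D3:**
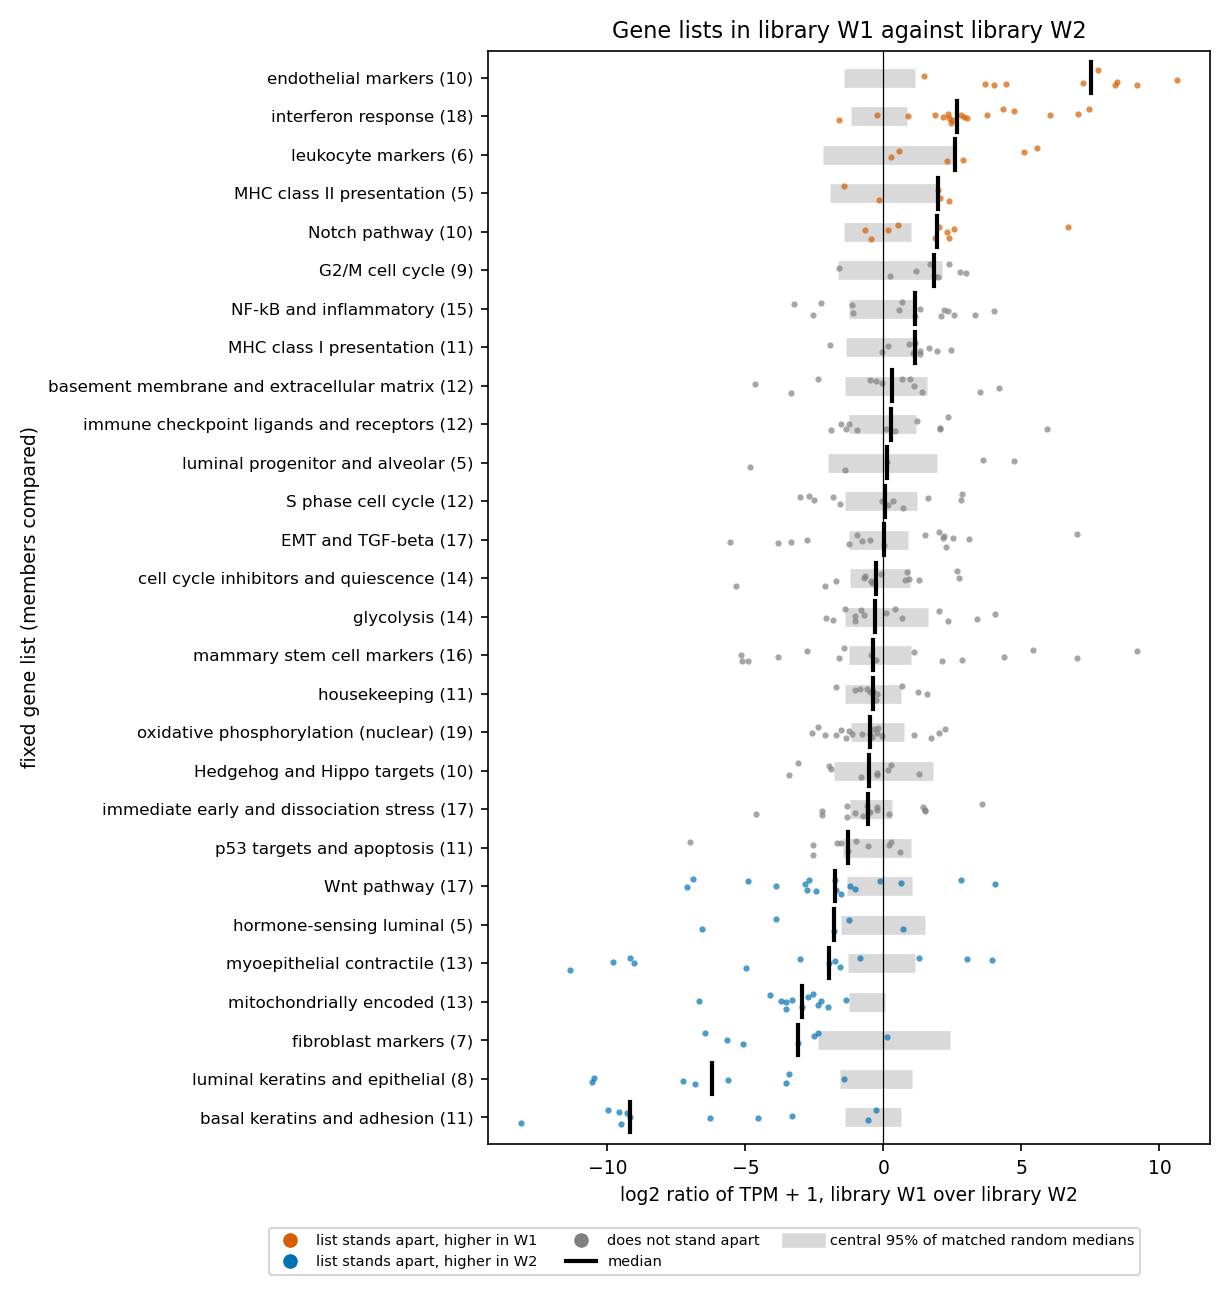
Each point is a gene's log2 ratio of TPM + 1, library W1 over library W2, on the horizontal axis, for the 28 fixed lists with at least 5 compared members on the vertical axis, where black bars are medians and grey bands hold the central 95% of 10000 matched random medians. Of these lists, 5 stood apart toward library W1, led by endothelial markers (median 7.51), and 7 toward library W2, led by basal keratins (median -9.20).

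Over the fixed lists, 28 of 31 had enough members for a percentile, 5 stood apart toward library W1, 7 stood apart toward library W2 and 16 did not stand apart. If members were independent random draws, 1.4 lists would be expected to stand apart. Genes of a list need not vary independently, and some lists share members such as Cdh5. The value of 1.4 is therefore not a chance rate for these lists. Medians on the TPM + 1 scale depend on the pseudocount where members have 0 reads in a library. With such genes set to the floor of 3 reads and no pseudocount, the medians toward library W1 were 8.68 for endothelial markers, 3.49 for interferon genes, 3.10 for leukocyte markers, 2.24 for Notch genes and 1.75 for MHC class II genes. Toward library W2 they were -9.18 for basal keratins, -6.51 for luminal keratins, -4.72 for fibroblast markers, -3.99 for contractile genes, -3.26 for hormone-sensing genes, -2.98 for mitochondrially encoded genes and -2.31 for Wnt genes.

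Library W1 had 10212 genes at 1 TPM or more and library W2 had 9179. The 10 most abundant genes took 47.5% of TPM in library W1 and 23.3% in library W2, and the 100 most abundant took 66.7% and 55.2%. Gm23935, described below, alone held 27.74% and 4.13% of TPM, from 1.56% and 0.19% of reads. Most of the gap for the 10 most abundant genes lies in this short transcript, so it does not show that library W1 is less complex. Ribosomal protein genes held 1.43% and 2.90% of TPM, and processed pseudogenes held 13.94% and 22.84%. Genes with many overlapping isoforms were undercounted, so these shares are not true shares of the RNA. The 10 genes with the highest mean TPM are named without ranking them, since counting was uneven between genes. They were Gm23935, annotated as a microRNA of 57 bases with identical copies elsewhere, at 277440 and 41321 TPM, the predicted gene Gm37376 (53275 and 11378 TPM), B2m, mt-Co1, the ferritin gene Fth1 (19961 and 20759 TPM), mt-Cytb and Ifitm3 (11849 and 19249 TPM). The ribosomal RNA gene CT010467.1 (19130 and 8159 TPM), the pseudogene Gm14303 (12638 and 12506 TPM) and mt-Nd1 were the others. Gm23935 and Gm14303 have 0 50-mers of their own, so their values are uncertain. The value of Gm37376, annotated on the plus strand, is uncertain as well. The use of strand is not given, so its reads cannot be told apart from those of any transcript on the other strand.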

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

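The restrictions to protein-coding genes, to genes with 1 listed transcript and to genes with at least 20 reads were chosen after the data were seen, and the other alternatives before. The counts of genes higher in library W1 and in library W2 (4370 and 4142) changed by over 1.5 times with a pseudocount of 5 (2112 and 2509), a 4-fold threshold (2292 and 2020), genes at 1 TPM or more in both libraries (1132 and 1968), protein-coding genes (2877 and 2760) and genes with 1 listed transcript (1711 and 1764). A filter at 5 TPM gave 2466 higher in library W1, and a minimum of 20 reads gave 2664. Fewer genes entered under each filter, and a 4-fold threshold or a pseudocount of 5 can only lower these counts. Rescaling moved the median log2 ratio of all genes from -0.07 to 0.26 with the median ratio, to 0.23 with FPKM and to -0.26 without mitochondrially encoded and ribosomal protein genes. The share of changed genes that were higher in library W1 was 51.34% as reported and 58.83%, 57.32% and 47.88% under these scalings.

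Among genes with 1 listed transcript, 0 lists stood apart toward library W1 and 4 toward library W2, and 5 lists kept enough members for a percentile. The endothelial, interferon, Notch, leukocyte and MHC class II lists, those reported toward library W1, all had too few such members for a percentile. The value of 0 toward library W1 was therefore fixed in advance and tells nothing about that direction. The contractile, hormone-sensing and fibroblast lists also had too few. No list that stood apart changed sign under any alternative run. The basal keratin list stood apart under every alternative, and the endothelial and contractile lists under every alternative that gave them a percentile. In the other lists, 226 alternative values gave the reported call, 11 brought a list past the limit (MHC class I, NF-kB and G2/M lists) and 9 took one back (MHC class II, leukocyte and hormone-sensing lists).

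The log2 ratio of Cd274 was 9.21 with a pseudocount of 0.1 and 3.68 with 5, against 5.91, since the gene has 0 reads in library W2. Pearson r across genes, 0.549, was 0.328 and 0.681 with these pseudocounts and 0.422 with a filter at 5 TPM. Library W1 had 6353 genes at 5 TPM or more, against 10212 at 1 TPM, and a higher limit can only lower this count. The cause of the changes in Pearson r was not tested further. Depth limits genes with few reads: a gene with 0 reads in a library may hold up to 3 there, and 2-fold calls on genes under 20 reads rest on few reads.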

Other observations

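The tests of explanations in this part were all chosen after the values had been seen, as were both added lists. Both lists were put together once endothelial genes had been seen to be higher in library W1, so their counts are no independent evidence of that direction. Of 10 compared members of the list of lymphatic endothelial genes, 7 were higher in library W1 and 1 in library W2 (median log2 ratio 3.66, and 5.12 with genes at 0 reads set to the floor). Lyve1 had 21085 and 0 reads, Prox1, a transcription factor of lymphatic endothelium, had 1801 and 0, and the growth factor receptor gene Flt4 had 768 and 0. Foxc2, a transcription factor of lymphatic valves, had 82 and 0 reads, and Sema3d stood at 20.6 and 0.468 TPM. Pdpn, which is made by lymphatic endothelium and by myoepithelial cells, stood at 438 and 531 TPM. The secreted protein gene Reln was the member higher in library W2, at 0.056 and 4.43 TPM.

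Venous and activated endothelial genes went the same way. Of 9 compared members of the second added list, 8 were higher in library W1 and 1 in library W2 (median 5.63, and 6.61 at the floor). Thbd had 12629 and 0 reads, the selectin genes Sele and Selp had 895 and 0 and 470 and 0, Icam2 had 368 and 0, and the chemokine-binding receptor gene Ackr1 had 292 and 0. Nr2f2, a transcription factor of veins, stood at 83.7 and 3.73 TPM. Vcam1 was 2.09-fold higher in library W1 (1.98 to 2.21), and the homing receptor ligand gene Madcam1 was 6.34-fold higher (4.70 to 8.69). Marco, a scavenger receptor gene, had 3087 and 0 reads. Xist, made from the inactive X chromosome of female cells, was read in both libraries, at 40.3 and 22.0 TPM.

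Library W1 is labelled as basal cells, yet most basal and luminal epithelial transcripts were lower in it than in library W2 and endothelial ones were higher. Exceptions were Itga6 (140 and 170 TPM) and Itgb1 (81.8 and 120 TPM), within 2-fold, and Cd24a kept 251 TPM. For the epithelial genes, loss of reads shared between isoforms is argued against. The 5 basal genes with 1 listed transcript had a median log2 ratio of -9.31, and the 5 luminal keratin list genes of this kind -7.26. The endothelial list has 2 genes with 1 listed transcript, too few for this test on the list. These are Cldn5 (6822 and 0 reads) and Plvap (11783 and 29 reads), and their values argue against such a loss for these 2 genes alone. Basal cells with a minor admixture of endothelial cells are argued against as well, because the basal and contractile lists summed to 327 TPM in library W1 and 47264 TPM in library W2, or 0.693%. All 10 compared endothelial markers were higher in library W1, with Plvap at 1957 TPM and Cldn5 at 1590 TPM. Which cells its material came from was not tested and stays open, as do a wrong label and a swap with an outside sample. Whether the gate removed Cd31 positive cells is not given in the sources used here. No difference between Pd-l1 classes could be tested, and these bulk values do not show which cells the Cd274 reads came from.

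The lymphatic chemokine gene Ccl21a was at a like level in both libraries (10177 and 7543 TPM, 26827 and 20018 reads). Reads or cells carried over from the material of library W1 are argued against. With the floor of 3 reads, the 10 compared endothelial markers had in library W2 a median of 0.2457% of their reads in library W1 and at most 17.6%, while Ccl21a had 74.6%. Reads from near-identical Ccl21 copies cannot be told apart from those of Ccl21a, because 233 of its 821 50-mers, 28.4%, are found in no other listed transcript. Other cells that make Ccl21a in library W2 stay open and were not tested.

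Mitochondrially encoded messenger RNAs were lower in library W1, at 2.41% of reads (2.39 to 2.42) against 12.76% (12.73 to 12.80) in library W2. A larger TPM share of short non-coding transcripts such as Gm23935 is argued against, because the shares of reads, which give no extra weight to short transcripts, had a log2 ratio of -2.41. Reads shared with other transcripts of mitochondrial sequence are argued against too, since the 6 members with over 500 50-mers of their own had a median log2 ratio of -2.47. Fewer mitochondria as the whole cause is argued against by the mitochondrial ribosomal RNAs mt-Rnr1 (7323 and 7256 TPM) and mt-Rnr2 (8220 and 9052 TPM), with a mean log2 ratio of -0.06, though a difference in how ribosomal RNA entered the libraries could hide such a change. A difference between cell types and one between Pd-l1 classes stay open and were not tested.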
